A study of Mus musculus with 24 samples.

How the data were processed

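XR-seq libraries of mouse kidney and liver were analysed from the read counts that the authors deposited. Each library holds oligomers released by nucleotide excision repair, which per the labels' protocols were captured with antibodies against the repair factor TFIIH and then with antibodies against a DNA lesion. The extraction protocol names lesions other than cisplatin adducts at that step, while the treatment protocol and the series' design text name cisplatin. The genome build mm10 is that of the submitters' processing notes, and the aligner and the counting tool are not given in the sources used here. The full tables list, per the file headers, a count of reads and an RPKM value for each gene, strand and time, in 1 table per tissue, strand and replicate number. The deposited count values are whole numbers and were used for every test. The deposited RPKM values were used only to recover each library total, from their ratio to count and gene length. Further tables of kidney counts, which the authors had drawn down to a fixed total (8700000 reads for replicate 1 and 20000000 for replicate 2), cover the transcribed strand (TS), the non-transcribed strand (NTS), overlapping genes and intergenic regions. The last 2 classes list each region on 2 lines, which were summed.

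The 24 libraries fall into 2 tissues, 6 zeitgeber times and 2 replicates per time, by their titles. The full tables hold 25239 gene entries. Of these 24203 name 1 symbol, 154 name several and 882 name none. Entries without a symbol took 2.76% of TS reads and were left out. Symbols were matched to the RefSeq names of GRCm38.p6, which held 24110 of the 24203. Coordinates are those of the authors' tables, 1-based. Of the entries, 3641 overlap another on the opposite strand and 3366 overlap one on the same strand, so that reads in the shared part cannot be assigned with certainty, and the reads of genes with close paralogues are uncertain for the same reason, which is said beside those of the Mup, Cyp2, Cyp4a, Ces1, Serpina3 and renin families. Precision follows from the depth: TS reads numbered 6334958 to 24236776 per kidney library and 9538537 to 21050661 per liver library, and NTS reads 975978 to 3948748 and 1333813 to 2940892.

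Counts were tested with edgeR 4.0.16 (limma 3.58.1, R 4.3.3), using glmQLFit and glmQLFTest after TMM scaling and filterByExpr, with Benjamini-Hochberg adjustment and a threshold of 0.05. Rhythms were tested per tissue and strand with the cosine and sine of a 24 h period. The amplitude is that of the log2 count, so that the fold between peak and trough is 2 to the power of 2 amplitudes. Its standard error for a named gene is the amplitude divided by the square root of F, from a test along the fitted peak. For the shares of genes more than 2 standard errors above a value, it was taken as the amplitude divided by the square root of 2 F. Dusk against dawn is the mean of ZT8 and ZT12 minus the mean of ZT20 and ZT0, with 1 mean per time in the model. TS was set against NTS in a model with 2 columns per library, the library as a block and 1 size for both strands, and the rhythm of the TS/NTS ratio is the interaction of strand and cosinor in that model. Kidney was set against liver as the mean over the 6 times, and the difference of rhythms as the interaction of tissue and cosinor. Named genes are given in CPM on the TMM scale, relative to the reads of the counted strand alone. Shares of reads per library were tested with 100000 permutations, of the times for the F statistic of the 24 h fit and of the tissue, 2-sided, for the difference of means. The smallest p possible is 1e-05. Read density is the number of reads of a class per kilobase of its total length, scaled to the reads of the 4 classes as in RPKM.

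Gene lists were tested in the dusk and dawn contrast with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. The 19 lists cover clock activators with genes of their phase such as Cry1 and Nfil3 (the clock activator list), clock repressors with E-box or D-box genes (the clock repressor list), nucleotide excision repair, p53 targets, immediate early genes, heat shock, platinum transport and thiol defence, xenobiotic metabolism, cholesterol, fatty acid synthesis, fasting, kidney tubule transport, hepatocyte genes, and markers of endothelial, immune, mesenchymal, podocyte, cholangiocyte and pancreatic acinar cells. The tests, the lists and the alternatives were chosen before the data were examined, except those named below as chosen after seeing the data.

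Genes named in the text follow a rule. For TS rhythms these were the 12 largest amplitudes among called genes with a mean of at least 20 reads and the same direction in each replicate number, up to 4 called members of each list, and all members of the clock and nucleotide excision repair lists. For dusk and dawn they were the 6 largest each way, for tissues the 8 largest each way, for strands the 8 largest and 4 smallest ratios, and elsewhere the 6 smallest p-values. RIKEN, Gm and miRNA models were skipped in favour of the next named gene. Some genes that the rule takes are not reported here.

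The tests were tested on simulated data with 200 changed genes drawn at the depth of the real libraries. The changed genes were taken from those with a mean of at least 20 reads. With changed genes taken from all 19277 kidney genes tested, 74.8% of TS rhythms of log2 0.5 were recovered. Libraries were simulated as independent, so the values below do not cover kidney libraries that deviated together by replicate number. The median amplitude called in the real kidney TS data was log2 0.21. Of genes with a log2 size of 0.5, the test recovered 93% for kidney TS rhythms, 72% for liver TS rhythms, 74% and 44% for dusk against dawn in kidney and liver, 87% for TS between tissues and 70% for the difference of rhythms. At a log2 size of 1 these were 100%, 99%, 96%, 81%, 100% and 97%. False calls made up 8.1%, 5%, 8.6%, 7.41%, 5.08% and 10.7% of the calls in the same order, against a threshold of 5%. For NTS rhythms the recovery at 0.5 was 83% in kidney and 79% in liver (8.5% and 8.67% false), and for ratio rhythms 56% and 58% (9.36% and 5.99% false). The regrouping of the tissues for the difference of rhythms was tested on simulated sets of 19702 genes with the real tissue means. With 200 genes rhythmic in kidney alone the real grouping called 201 and the highest of the others 54, and with 200 genes that followed another grouping that one called 207 and the real one 0. These simulated rhythms had a log2 amplitude of 1, against a median of 0.468 for the differences called in the real data.

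Kidney samples with the same replicate number deviated together from their time means (correlation 0.134 to 0.383 in 15 of 15 pairs over 0.1). The number was therefore treated as pairing kidney samples, and a value with the replicate number as a block is given beside those kidney results of the text whose call it changed or whose count it moved by over 1.5 times. In liver 6 of 15 pairs were over 0.1 (-0.141 to 0.228), and between kidney and liver 3 of 6, so the numbers were not taken to pair those samples. All negative liver values involved ZT0, and pairs of the other times ranged from 0.048 to 0.201. A weaker pairing of liver samples is therefore not excluded, and the main liver tests do not account for it.

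Alternatives comprised another scaling, library sizes from TS plus NTS reads, other filters on low counts, DESeq2 1.42.0, any difference among the 6 times, a stricter threshold of 0.01, the downsampled kidney tables, the replicate block and each library left out in turn. Added after seeing the data were the NTS share of the library as a covariate, the removal of genes overlapping the opposite strand, and the replicate block for shares of reads. A correction for gene length was added later still: a smooth trend of each library's log2 CPM over gene length, relative to the mean of the libraries, was taken into the offsets of the kidney and liver TS rhythm fits, and in kidney also of the fit with the replicate block. It was tested on 6 simulated kidney sets of 19277 genes with a length trend that followed the day. Of the calls 84.3% were false without the correction and 7.40% with it, against 5.17% where no trend was simulated.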

Results

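Excision repair of cisplatin adducts was mapped in mouse kidney and liver across the day with XR-seq. This assay sequences the short oligomers that nucleotide excision repair cuts out of damaged DNA, so that each read marks a site where an adduct was being removed. Female C57BL/6J mice, 6 months old and kept in 12 h of light and 12 h of dark, received 10 mg/kg of cisplatin by intraperitoneal injection, and tissue was taken 2 h later at zeitgeber times (ZT, hours after lights on) 0, 4, 8, 12, 16 and 20. Each tissue had 2 libraries per time, which made 12 kidney and 12 liver libraries. Library totals ranged from 8718055 to 33716763 reads in kidney and from 12917058 to 28244795 in liver. Reads on the transcribed strand (TS) of genes, where RNA polymerase stalls at damage, numbered 6334958 to 24236776 per kidney library and 9538537 to 21050661 per liver library. Reads on the non-transcribed strand (NTS) numbered 975978 to 3948748 and 1333813 to 2940892. The labels do not say whether the 2 libraries of a time came from separate mice, so p-values measure only the spread between these libraries, which may be technical, and any error from read counts alone covers counting error only. The series title names 2 circadian programs of repair in transcribed genes, so the main comparisons were those among the times of day.

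Repair was concentrated on the transcribed strand in both tissues. In kidney 15531 of 19756 genes tested had more TS than NTS reads and 2184 had fewer, with a median TS/NTS ratio of 5.05 (log2 2.34, 12 libraries). Liver gave 15007 higher and 2167 lower genes of 19256, with a median ratio of 5.69 (log2 2.51). Endov, which encodes an endonuclease, had 45.6 times more TS than NTS reads in kidney (log2 5.51 ± 0.10 SE), and Ncln had 45.1 times more (log2 5.49 ± 0.12). Both were higher on the TS in 12 of 12 libraries. Msantd4 (log2 5.81 ± 0.18), Borcs8 (log2 5.54 ± 0.12) and Elof1 (log2 6.14 ± 0.16), a transcription elongation factor, had the other large kidney ratios. The last 2 share part of their span with another gene of the same strand, so their reads cannot be assigned with certainty. In liver Slc39a3, a zinc transporter, had a log2 ratio of 6.07 ± 0.10 and Urm1 one of 6.00 ± 0.09. Capn15 (log2 6.56 ± 0.12), Elof1 (log2 6.48 ± 0.18), Dctn1 (log2 6.01 ± 0.08) and Mcrs1 (log2 6.22 ± 0.10) were as high but overlap another gene.

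Snord100, Snord88c and Snora5c in kidney and Olfr267 and Snord88c in liver also stood among the genes with the largest ratio, on 4 or fewer NTS reads over all libraries, and no fold is given for them. Most genes named here for the opposite ratio overlap another gene's span. Col10a1 had 78.7 times fewer TS than NTS reads in kidney (log2 -6.30 ± 0.13) and 111 times fewer in liver (log2 -6.79 ± 0.11). Gcnt7 (log2 -5.84 ± 0.14), Cxcr6 (log2 -5.79 ± 0.15) and Frs3os (log2 -5.56 ± 0.16) followed in kidney, and Zfhx2os (log2 -7.38 ± 0.18), Lhb (log2 -6.80 ± 0.18) and Msmp (log2 -6.68 ± 0.16) in liver. All of these but Lhb overlap an annotated gene of the opposite strand, whose transcribed strand is their non-transcribed one. The adjusted p was 4.89e-21 or smaller for each of these low genes by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. A scaling that centres the strands on each other (TMM over the strand columns) moved the median of all genes from log2 2.34 to 0.01 in kidney and from 2.51 to 0.10 in liver. With it 9233 kidney genes were higher and 9222 lower on the TS, and 9278 and 8764 liver genes.

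All 29 measured nucleotide excision repair genes had more TS than NTS reads in both tissues (median log2 3.74 in kidney and 3.58 in liver, adjusted over all genes and adjusted over the list alone). The same held for all 24 p53 target genes (median log2 3.39 and 3.58), which respond to DNA damage. It held as well for all 15 heat shock and all 18 fasting genes. Of all genes tested 89.67% in kidney and 89.19% in liver differed between the strands in either direction. The repair and p53 lists did not pass an unplanned test for a larger share (Fisher's exact test, adjusted p = 0.401 and 0.462 in kidney, 0.342 for both in liver). Genes of tissue-specific programs followed the tissue: 30 of 30 hepatocyte genes were higher on the TS in liver (median log2 3.22) against 25 of 30 in kidney (median log2 1.31). Of the kidney tubule transport genes 30 of 30 were higher on the TS in kidney (median log2 2.56), against 11 of 27 in liver, where 8 were lower (median log2 0.28). These differences between tissues were not tested on the ratio itself.

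The share of genic reads on the TS was 85.9% ± 1.23 (SD, n = 12) in kidney and 87.5% ± 0.737 (SD, n = 12) in liver. The liver mean was above the kidney mean at 6 of 6 times, by 1.60 points on average (kidney minus liver -1.60, 2-sided permutation test, p = 0.00086). In liver the share was highest at ZT20 (88.4% ± 0.872) and lowest at ZT8 (86.8% ± 0.962), with a fitted 24 h amplitude of 0.747 ± 0.221 points and a peak at 19.1 h (permutation p = 0.016, adjusted over the 2 tissues 0.032). With the replicate number as a block, a setting chosen after seeing the data, the liver test gave a permutation p of 8e-05. Taken as the median over genes of log2 TS/NTS, the liver rhythm did not pass (permutation p = 0.068). Without liver ZT20 replicate 1 the amplitude was 0.574 (permutation p = 0.071) and without liver ZT8 replicate 2 it was 0.617 (permutation p = 0.057). In kidney the share was also highest at ZT20 (87.3% ± 1.02) and lowest at ZT8 (84.4% ± 1.17), with an amplitude of 1.13 ± 0.409 points and a peak at 20.0 h, which did not pass the test (permutation p = 0.065, adjusted 0.065). With the replicate number as a block, the kidney test gave a permutation p of 0.0079. Without kidney ZT0 replicate 2 the amplitude was 1.36 (permutation p = 0.012) and without kidney ZT4 replicate 1 it was 1.31 (permutation p = 0.030).

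**Figure D1:**
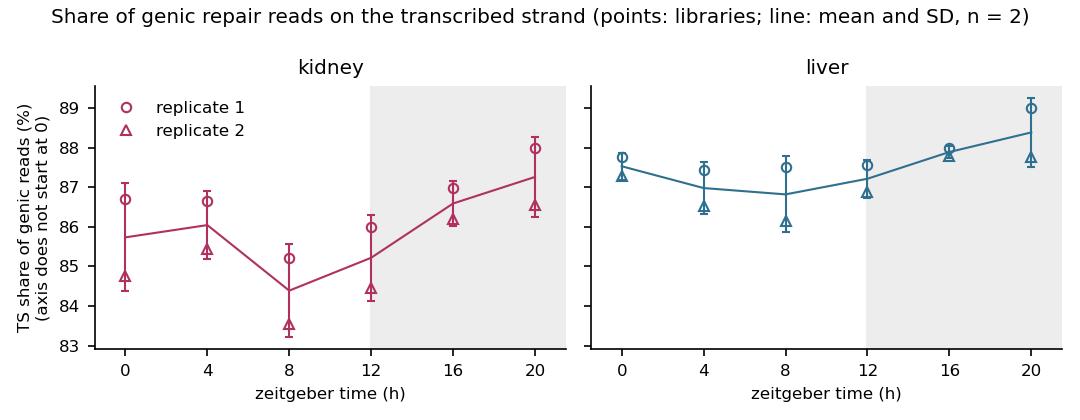
Share of genic repair reads on the transcribed strand (percent, axis not starting at 0) against zeitgeber time (h) in kidney and liver. Open points are libraries, lines and bars are means and SD of 2 libraries, the grey area is the dark phase, and the means were highest at ZT20 (87.3% in kidney, 88.4% in liver) and lowest at ZT8 (84.4% and 86.8%).

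In kidney, TS reads of clock genes were among those with the widest rhythm over the day. Npas2, a transcriptional activator of the circadian clock, fell from 261 ± 3.16 TS counts scaled to library size (CPM; SD, n = 2) at ZT20 to 34.5 ± 1.84 at ZT12. Its fitted amplitude was log2 1.68 ± 0.06 (SE), a 10.2-fold range between peak and trough, with a peak at 22.5 h (adjusted p = 8.17e-11, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Npas2 lies on chromosome 1 from 39194272 to 39363240 on the plus strand (mm10). Arntl, which encodes the core activator BMAL1 (chromosome 7, 113207465 to 113314126, plus strand), had an amplitude of 1.11 ± 0.11 and a peak at 22.1 h, with 405 ± 3.19 CPM at ZT20 and 93.4 ± 19.2 at ZT8. The repressor-phase genes peaked about 12 h apart from these: Ciart at 10.8 h (amplitude 1.15 ± 0.08) and Dbp, a D-box transcription factor, at 10.2 h (0.93 ± 0.07). Ciart and Dbp overlap a gene of the opposite strand, so part of their reads may stem from repair of that gene. Thbs4 (1.23 ± 0.12, peak 13.3 h), Lingo4 (1.06 ± 0.08, 15.5 h), Insc (0.75 ± 0.06, 20.3 h) and the carboxylesterase Ces1d (0.74 ± 0.07, 12.0 h), whose reads are uncertain because of close paralogues, were the other large rhythms that were kept without any single library. Armc12 (0.82 ± 0.15, 8.9 h) and Serpina16 (0.80 ± 0.13, 7.4 h) also kept their calls. The calls of Gpr55 (0.79 ± 0.17) and Hrh4 (0.75 ± 0.16) were lost without kidney ZT16 replicate 1 (adjusted p = 0.0574) and without either ZT8 library (up to 0.11), respectively.

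Over all genes, 2885 of 19277 were called rhythmic in kidney TS reads at an adjusted p of 0.05, with a median amplitude of log2 0.21 (1.34-fold between peak and trough). Their peaks fell into 2 windows: 2016 genes (69.9%) peaked between 16 and 24 h, 808 (28.0%) between 4 and 12 h, and 61 elsewhere. The median gene length was 77.0 kb in the first of these groups, 13.1 kb in the second and 20.9 kb over all genes tested. After each library's trend over gene length was removed, a setting chosen after seeing the data, 1975 genes were called, and the lengths were 42.4 kb for the 1338 that peaked between 16 and 24 h and 33.6 kb for the 573 between 4 and 12 h. Of the clock activators and genes of their phase, 5 of 7 were called (7 adjusted over the list alone). Besides Npas2 and Arntl these included Cry1 (0.68 ± 0.08, 16.6 h) and Clock (0.21 ± 0.04, 19.8 h). Nfil3 (0.11 ± 0.04, adjusted p = 0.111) and Rora (0.14 ± 0.05, adjusted p = 0.103) did not pass, though Rora did with the replicate number as a block (adjusted p = 0.0138). Of the clock repressors and E-box or D-box genes, 11 of 14 were called (14 adjusted over the list alone). Among them were Nr1d1, the nuclear receptor REV-ERBα (0.71 ± 0.08, 6.7 h), Nr1d2 (0.33 ± 0.04, 8.3 h), Per3 (0.49 ± 0.04, 11.3 h), Per2 (0.35 ± 0.06, 13.6 h) and Tef (0.41 ± 0.04, 9.7 h). Nr1d1 overlaps an opposite-strand gene. The Clock call was lost without kidney ZT8 replicate 2 (adjusted p = 0.0552) and with the length trend removed (amplitude 0.13, adjusted p = 0.0541).

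**Figure D2:**
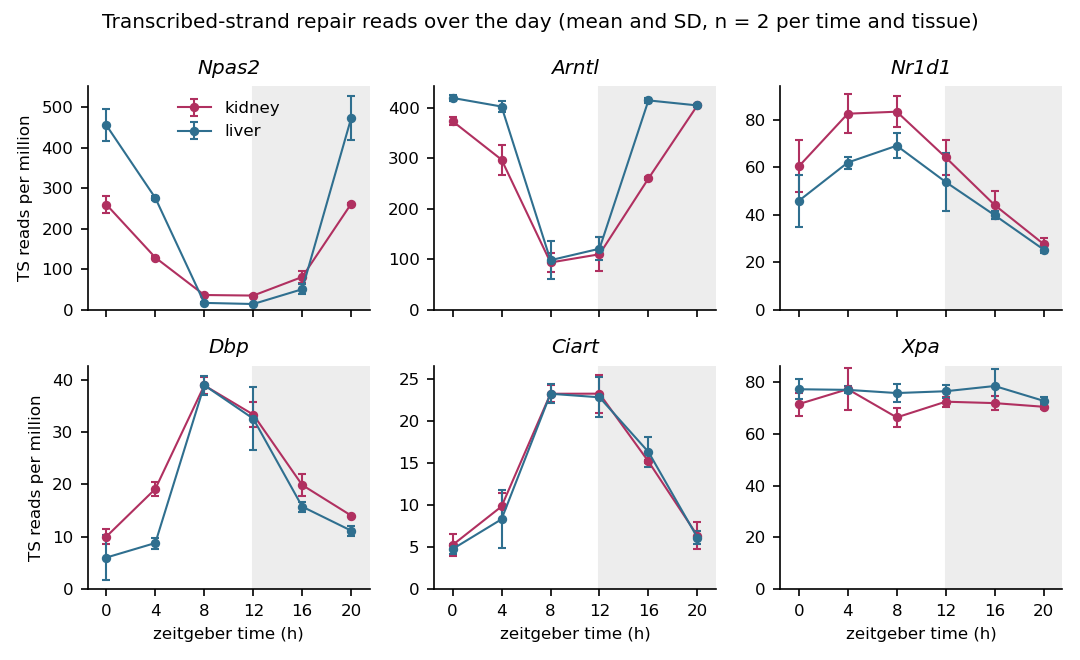
Transcribed-strand reads in CPM against zeitgeber time (h) for 5 clock genes and Xpa in kidney (red) and liver (blue), as means with SD of 2 libraries, with the dark phase in grey. Npas2 fell from 261 at ZT20 to 34.5 at ZT12 in kidney and from 473 to 13.7 in liver, while Xpa lay between 66.3 and 78.5 throughout.

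Of all kidney genes tested 14.97% were called rhythmic. Only the clock activator, clock repressor and endothelial lists passed a test for a larger share (Fisher's exact test, adjusted p = 0.0115, 3.69e-06 and 0.0137). The repair list did not (adjusted p = 0.948). This test was not planned, treats genes as independent and was not run with the replicate number as a block. Of 29 nucleotide excision repair genes 3 were called rhythmic in kidney (1 adjusted over the list alone): Mnat1 (0.20 ± 0.04, 18.8 h) and Gtf2h2 (0.18 ± 0.05, 19.2 h), which encode parts of TFIIH, and the damage sensor Ddb1 (0.13 ± 0.03, 7.3 h). The Mnat1 call was lost without kidney ZT20 replicate 1 or either ZT8 library (adjusted p up to 0.0973). Those of Gtf2h2 (up to 0.19) and Ddb1 (up to 0.14) were lost without ZT4 replicate 2, ZT12 replicate 2, ZT16 replicate 1, ZT20 replicate 1 or either ZT8 library, and that of Gtf2h2 also without ZT20 replicate 2. With the length trend removed, Mnat1 (amplitude 0.10, adjusted p = 0.124) and Ddb1 (0.12, adjusted p = 0.0583) did not pass. Xpa, a damage-verification factor (chromosome 4, 46175222 to 46196311, minus strand), had an amplitude of 0.02 ± 0.04 (adjusted p = 0.909) with 66.3 ± 3.72 CPM (SD, n = 2) at ZT8 and 77.2 ± 8.00 at ZT4. Of the p53 target genes 7 of 24 were called (10 adjusted over the list alone), among them the apoptosis gene Bbc3 (0.24 ± 0.05, 3.9 h). Of the immediate early genes 5 of 15 were called (7 over the list alone), all with a peak between 4 and 12 h, such as the growth-response factor Egr1 (0.31 ± 0.06, 7.6 h). Heat shock genes gave 2 of 15, genes of platinum transport and thiol defence 1 of 21 (the efflux pump Abcc4, 0.25 ± 0.04, 19.7 h), with the same counts adjusted over the list alone.

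Of the fasting genes 6 of 18 were called rhythmic in kidney (9 adjusted over the list alone), all between 4 and 12 h, such as Pdk4 (0.31 ± 0.05, 6.5 h), which slows glucose oxidation, and Angptl4 (0.44 ± 0.08, 7.7 h), a lipase inhibitor. The fatty acid hydroxylases Cyp4a10 (0.33 ± 0.05, 8.4 h) and Cyp4a14 (0.40 ± 0.08, 8.7 h) were among 4 of 20 xenobiotic genes called (5 over the list alone), and both have close paralogues, so their reads are uncertain. Of the fatty acid synthesis genes 3 of 17 were called (3 over the list alone), 1 between 4 and 12 h and 2 between 16 and 24 h, such as Acaca, the first committed enzyme of fatty acid synthesis (0.44 ± 0.06, 17.9 h). Of the cholesterol genes 4 of 20 were called (5 over the list alone), 1 between 4 and 12 h and 3 between 16 and 24 h, such as Fdps (0.28 ± 0.04, 19.3 h) and Lss (0.28 ± 0.04, 17.8 h). Of the kidney tubule transport genes 5 of 30 were called (6 over the list alone), led by the urate transporter Slc22a12 (0.25 ± 0.05, 5.9 h). Among markers of other cell types, 7 of 14 endothelial markers were called (11 over the list alone), 6 of them between 4 and 12 h, such as Eng (0.30 ± 0.05, 8.0 h), and Stab2 at 22.7 h (0.33 ± 0.05). Called fractions were 2 of 14 immune (2 over the list alone), 2 of 11 mesenchymal (6), 1 of 7 podocyte (2), 1 of 7 cholangiocyte (1) and 3 of 30 hepatocyte genes (3). Examples were the mesenchymal Pdgfrb (0.35 ± 0.08, 7.8 h), the podocyte Podxl (0.24 ± 0.04, 7.6 h) and the cholangiocyte Cftr (0.42 ± 0.06, 19.8 h), and the hepatocyte gene Alb (0.57 ± 0.11, 13.1 h) was called on a mean of 61 reads.

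The kidney count depended on single libraries: 1688 genes were called without ZT16 replicate 1, 1703 without ZT20 replicate 1, 1868 without ZT4 replicate 2, 1328 without ZT8 replicate 1 and 908 without ZT8 replicate 2. With the replicate number as a block it rose to 4900, and called list members numbered 7 of 29 repair, 8 of 15 immediate early, 6 of 15 heat shock and 3 of 21 platinum and thiol genes. With that block 7 of 20 xenobiotic, 6 of 17 fatty acid, 10 of 30 tubule and 5 of 30 hepatocyte genes were called, and 5 of 11 mesenchymal, 3 of 7 podocyte and 2 of 7 cholangiocyte markers. A test for any difference among the 6 times called 196 genes, and the NTS share as a covariate left 724. Of the 70 named kidney genes 40 kept their call without any single library, and 20 also under every other setting at the threshold of 0.05.

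In liver the largest TS rhythm was also that of Npas2, which fell from 473 ± 53.5 CPM (SD, n = 2) at ZT20 to 13.7 ± 0.357 at ZT12, a fitted 64.3-fold range (SE of the log2 amplitude 0.21, peak 23.2 h, adjusted p = 3.06e-05, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Arntl had an amplitude of 1.09 ± 0.22 (21.9 h), Dbp 1.30 ± 0.19 (11.0 h), Ciart 1.27 ± 0.11 (11.2 h) and Bhlhe41, a clock repressor, 1.04 ± 0.16 (10.2 h). Outside the clock, Loxl4, a lysyl oxidase of the matrix, peaked at 22.9 h (1.31 ± 0.10) with 77.4 ± 19.4 CPM at ZT0 and 16.0 ± 1.79 at ZT12. The peptidase gene Mme peaked at 13.8 h (1.16 ± 0.14), the matrix gene Npnt at 0.1 h (1.14 ± 0.20), Rnf144a at 23.0 h (1.09 ± 0.11) and the zinc finger gene Zbtb7c at 21.5 h (1.06 ± 0.18). The water channel gene Aqp4 (1.10 ± 0.18, 9.8 h), Tmem171 (1.04 ± 0.17, 0.0 h) and Ppp1r3g (1.04 ± 0.19, 9.1 h), which directs glycogen storage, completed the largest rhythms. Rnf144a and Zbtb7c overlap a gene of the opposite strand, and Rnf144a also one of its own. All of these genes kept their call without any single library.

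Over all genes, 3098 of 18655 were called rhythmic in liver TS reads, with a median amplitude of log2 0.22 (1.35-fold). Of these 1802 (58.2%) peaked between 16 and 24 h, 1144 (36.9%) between 4 and 12 h and 152 elsewhere, and the median gene length was 46.8, 16.9 and 21.9 kb in the first group, the second and all genes tested. After each library's trend over gene length was removed, the lengths were 24.8 kb for the 1338 genes then called between 16 and 24 h and 23.3 kb for the 837 between 4 and 12 h. Of the clock activator list 6 of 7 were called (7 adjusted over the list alone), with Nfil3 in the opposite window (0.26 ± 0.04, 9.2 h) from Clock (0.30 ± 0.05, 21.1 h) and Cry1 (0.27 ± 0.06, 18.0 h). Rora did not pass (0.10 ± 0.04, adjusted p = 0.131). Of the clock repressor list 11 of 14 were called (13 over the list alone), such as Per3 (0.82 ± 0.11, 12.4 h), Usp2 (0.57 ± 0.07, 13.1 h), Tef (0.53 ± 0.06, 11.6 h) and Nr1d1 (0.62 ± 0.09, 7.2 h). Per2 (0.56 ± 0.13, 13.5 h, adjusted p = 0.0228) was called but not without liver ZT0 replicate 2 or ZT4 replicate 2 (adjusted p up to 0.0526).

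**Figure D3:**
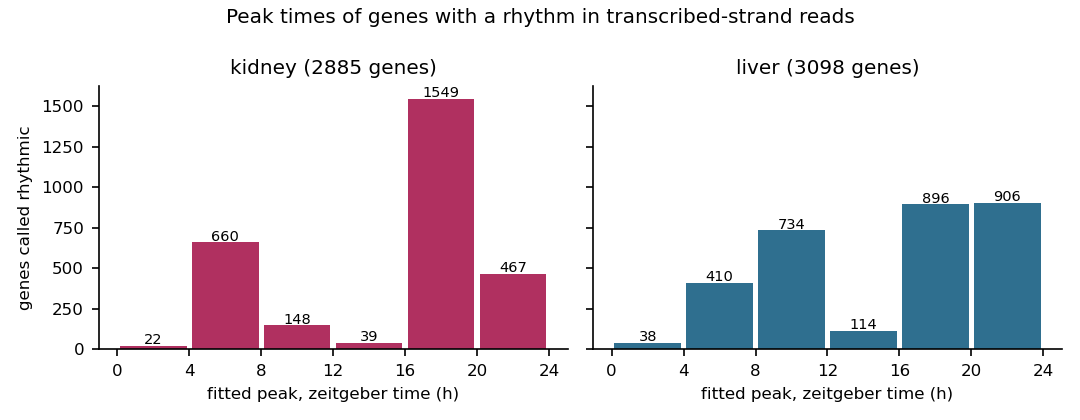
Number of genes called rhythmic in transcribed-strand reads by fitted peak time, in bins of 4 h, for kidney (2885 genes) and liver (3098 genes). The bars from 16 to 24 h held 2016 kidney and 1802 liver genes, and those from 4 to 12 h held 808 and 1144.

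Of all liver genes tested 16.61% were called rhythmic. Only the clock activator and clock repressor lists passed the same unplanned test for a larger share (Fisher's exact test, adjusted p = 0.00119 and 1.1e-05). The repair list did not (adjusted p = 0.945). In liver 6 of 29 nucleotide excision repair genes were called (6 adjusted over the list alone), and 5 of them peaked between 16 and 24 h. Rpa1, a subunit of the single-strand binding protein (0.27 ± 0.04, 20.5 h, adjusted p = 0.00225), and Mnat1 (0.19 ± 0.03, 20.1 h) kept their calls without any single library, but Mnat1 did not pass with the length trend removed (amplitude 0.115, adjusted p = 0.248). Xpc, the damage recognition factor (0.13 ± 0.03, 20.2 h), lost its call without liver ZT20 replicate 1 and without liver ZT8 replicate 2 (adjusted p up to 0.0918). Rad23b (0.12 ± 0.03, 7.8 h) lost it without ZT12 replicate 2 or any ZT8, ZT16 or ZT20 library (adjusted p up to 0.111). Ercc1 (0.15 ± 0.04, 21.3 h) lost it without any library but ZT0 replicate 1 and ZT12 replicate 1 (up to 0.143), and Gtf2h2 (0.16 ± 0.04, 19.4 h) without any but the ZT0 libraries (up to 0.135). Xpa had an amplitude of 0.01 ± 0.03 (adjusted p = 0.964). Of the p53 target genes 8 of 24 were called (8 over the list alone), such as Gtse1 (0.59 ± 0.10, 9.0 h), and of the platinum and thiol genes 6 of 21 (6 over the list alone), such as Txnrd1 (0.15 ± 0.02, 7.7 h), which encodes thioredoxin reductase, and the glutathione synthesis gene Gclc (0.16 ± 0.03, 8.4 h).

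Of the liver cholesterol genes 5 of 22 were called (14 adjusted over the list alone), 4 of them between 4 and 12 h. The other was Cyp7a1, the rate-limiting enzyme of bile acid synthesis, at 14.0 h (0.68 ± 0.14). Fasting genes gave 6 of 18 (13 over the list alone), all between 4 and 12 h, such as Irs2 (0.23 ± 0.03, 9.1 h), an insulin signalling adaptor, and Got1 (0.20 ± 0.03, 9.0 h). Fatty acid synthesis genes gave 3 of 17 (5 over the list alone), and xenobiotic genes 4 of 21 (5), among them Cyp2c55 (0.77 ± 0.11, 22.2 h) and Ces1g (0.42 ± 0.07, 15.8 h), whose reads are uncertain because of close paralogues. Immediate early genes gave 2 of 15 (2), with the stress factor Atf3 at 7.4 h (0.31 ± 0.04). Hepatocyte genes gave 3 of 30 (3), kidney tubule genes 2 of 27 (1), immune markers 1 of 15 (1), podocyte markers 1 of 7 (1), cholangiocyte markers 1 of 7 (1) and acinar markers 1 of 3 (1). The liver count was 1639 without liver ZT20 replicate 1, 1817 without ZT20 replicate 2, 1907 without ZT8 replicate 1 and 2021 without ZT8 replicate 2. A test for any difference among the 6 times called 549 genes, and the NTS share as a covariate left 649. Of the 65 named liver genes called, 41 kept their call without any single library, and 16 also under every other setting at the threshold of 0.05.

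Of 18354 genes tested in both tissues, 1241 were called rhythmic in both, against 481.6 for independent lists, and 93.2% of these peaked within 3 h of each other (median difference 1.08 h). The value for independent lists is not one of no shared source: the labels do not say whether a kidney and a liver library of the same time and number come from 1 mouse, and both tissues had a trend of long against short genes of similar phase (amplitude log2 0.174, peak 18.4 h in kidney and 0.124, 20.4 h in liver). With that trend removed in each tissue, 648 genes were called in both, against 245.4 for independent lists. Peaks between 4 and 12 h in both tissues were seen for 279 genes (49.4 for independent lists) and peaks between 16 and 24 h in both for 878 (197). Genes with a kidney peak between 4 and 12 h and a liver peak between 16 and 24 h numbered 5 (78.3), and the reverse 18 (124).

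Dusk (mean of ZT8 and ZT12, 4 libraries) was set against dawn (mean of ZT20 and ZT0, 4 libraries). In kidney Npas2 had 7.38-fold more TS reads at dawn (dusk minus dawn, log2 -2.88 ± 0.08 SE, adjusted p = 2.56e-10, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Arntl (log2 -1.95 ± 0.12), Insc (-1.18 ± 0.11), Asxl3 (-1.04 ± 0.15), Slitrk1 (-1.07 ± 0.20) and the water channel gene Aqp8 (-1.01 ± 0.25) were also higher at dawn. Ciart was 3.93-fold higher at dusk (log2 1.98 ± 0.14), followed by Dbp (1.61 ± 0.09), Thbs4 (1.46 ± 0.18), Armc12 (1.40 ± 0.19) and Serpina16 (1.14 ± 0.23). Slitrk1 and Serpina16 (adjusted p up to 0.0867) lost their calls without ZT12 replicate 2 or ZT8 replicate 2. Both also lost them without ZT8 replicate 1, Slitrk1 without ZT20 replicate 2 and Serpina16 without ZT20 replicate 1. Aqp8 lost its call (up to 0.122) without any library but ZT0 replicate 2 and the ZT16 libraries. Over all genes 174 were higher at dusk and 959 at dawn, out of 19277. With library sizes from TS plus NTS reads the split was 340 higher and 561 lower, and with the NTS share as a covariate, a setting chosen after seeing the data, 203 and 312. With the replicate number as a block 1268 were higher and 2889 lower.

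As groups, the 14 clock repressors and E-box or D-box genes were higher at dusk in kidney (median log2 0.45, adjusted p = 5.67e-17 by limma's camera, adjusted p = 0.017 with an estimated correlation), with 10 called higher (11 adjusted over the list alone). Clock activators and genes of their phase were lower (median log2 -0.19, adjusted p = 0.000399, adjusted p = 0.059 with an estimated correlation), with 3 of 7 called (3 over the list alone). Fasting genes were higher (median 0.14, adjusted p = 0.00148, adjusted p = 0.322 with an estimated correlation). Immediate early genes (median 0.18, adjusted p = 0.0299) and heat shock genes (median 0.12, adjusted p = 0.00848) were higher too, each with an adjusted p = 0.689 with an estimated correlation. Markers of 3 other cell types moved the same way: endothelial (median 0.32, adjusted p = 2.03e-05), podocyte (0.34, adjusted p = 0.00205) and mesenchymal (0.36, adjusted p = 0.00344), each with an adjusted p = 0.464 with an estimated correlation. Eng (0.45 ± 0.09) was called higher at dusk, but not without kidney ZT12 replicate 2, ZT20 replicate 1 or ZT8 replicate 2 (adjusted p up to 0.0928), and Stab2 lower (-0.56 ± 0.09), but not without ZT12 replicate 2 or ZT8 replicate 2 (up to 0.0713). Endothelial markers counted 4 of 14 over all genes, 12 over the list alone and 12 with the replicate number as a block. The remaining 11 lists did not pass, with the nucleotide excision repair list at an adjusted p of 0.585 (median -0.04). Median and mean differed in sign for the xenobiotic (-0.07 and 0.03, adjusted p = 0.107 upward) and acinar lists (-0.05 and 0.12, adjusted p = 0.852 upward).

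The kidney dusk and dawn count varied widely with single libraries. It was 547 without ZT0 replicate 1, 4004 without ZT0 replicate 2, 94 without ZT12 replicate 2, 540 and 538 without ZT16 replicates 1 and 2, and 151 and 307 without ZT20 replicates 1 and 2. It was 684 without either ZT4 library and 260 and 101 without ZT8 replicates 1 and 2, against 1133 with all libraries. Of the 36 named genes called, 10 kept their call without any single library and under every other setting at the threshold of 0.05.

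In liver Npas2 had 31.1-fold more TS reads at dawn (log2 -4.96 ± 0.12, adjusted p = 6.53e-09, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Loxl4 (-2.22 ± 0.14), Arntl (-1.93 ± 0.14), Rnf144a (-1.85 ± 0.08), Zbtb7c (-1.82 ± 0.28) and Npnt (-1.78 ± 0.22) were also higher at dawn. Dbp (2.16 ± 0.24, 4.47-fold), Ciart (2.09 ± 0.18), Aqp4 (1.89 ± 0.35), the trehalase gene Treh (1.84 ± 0.32), Ppp1r3g (1.82 ± 0.23) and Bhlhe41 (1.81 ± 0.21) were higher at dusk. All 12 kept their call without any single library. Of all 51 named liver genes called, 25 did so, and 17 also under every other setting at the threshold of 0.05. Over all genes 874 were higher at dusk and 1420 at dawn, out of 18655, and with library sizes from TS plus NTS reads 1420 were higher and 1315 lower. With the NTS share as a covariate 378 were called. The count was 3574 and 5374 without ZT0 replicates 1 and 2, 948 and 1223 without ZT12 replicates 1 and 2, 679 and 1232 without ZT20 replicates 1 and 2, and 1105 and 915 without ZT8 replicates 1 and 2, against 2294 with all libraries.

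The clock repressor list was higher at dusk in liver (median log2 0.63, adjusted p = 6.22e-13 by limma's camera, adjusted p = 0.0352 with an estimated correlation), with 10 of 14 called (13 adjusted over the list alone). Fasting genes were higher (median 0.32, adjusted p = 4.25e-07, adjusted p = 0.515 with an estimated correlation), with 8 of 18 called higher (12 over the list alone), such as Irs2 (0.38 ± 0.06), Got1 (0.34 ± 0.07) and the gluconeogenic enzyme Fbp1 (0.36 ± 0.06). Cholesterol genes were higher (median 0.28, adjusted p = 1.69e-06, adjusted p = 0.515 with an estimated correlation), with 6 of 22 called (15 over the list alone). Fatty acid synthesis genes (median 0.19, adjusted p = 0.000395) had an adjusted p = 0.574 with an estimated correlation, hepatocyte genes (0.20, adjusted p = 0.000335) an adjusted p = 0.699 with an estimated correlation and heat shock genes (0.13, adjusted p = 0.047) an adjusted p = 0.515 with an estimated correlation. The list of clock activators and genes of their phase, with Nfil3 at dusk (0.44 ± 0.07) and Clock at dawn (-0.51 ± 0.06), did not pass (median -0.24, adjusted p = 0.129). Endothelial markers had a median of -0.24 in liver (adjusted p = 0.751). Of the repair list, 3 of 29 were called lower at dusk (5 over the list alone, 1 of them higher), led by Rpa1 (-0.43 ± 0.06), while the list did not pass (adjusted p = 0.625). Median and mean differed in sign for the repair (0.03 and -0.04), immune (-0.02 and 0.13), cholangiocyte (0.02 and -0.03) and acinar lists (0.02 and -0.15), and the podocyte list tested upward with a median of -0.08, none of which passed.

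Rhythms were also called in reads counted on the non-transcribed strand. Of the genes called, 40.4% in kidney and 27.0% in liver overlap a gene of the opposite strand, and 37.1% and 46.1% had their NTS peak within 3 h of their own TS peak. In kidney Per2, a core clock repressor, peaked on the NTS at 4.7 h (amplitude log2 0.66 ± 0.06 SE, adjusted p = 2.71e-06, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), while its TS peaked at 13.6 h. NTS reads of Per2 (chromosome 1, 91415982 to 91459328, minus strand) went from 290 ± 45.0 CPM (SD, n = 2) at ZT4 to 110 ± 8.41 at ZT16. These CPM are scaled to NTS reads alone and cannot be set against TS values. Scaled to the reads of both strands, Per2 had a kidney mean of 26.9 CPM on the NTS and 210 on the TS. Btbd10 (0.75 ± 0.08, 21.8 h) and Pdia2 (0.61 ± 0.08, 19.2 h) have no annotated opposite-strand overlap. Overlap was judged by annotated spans alone, so reads from a neighbouring gene past its annotated end are not excluded for either. Sphk2 (0.71 ± 0.07, 10.1 h), Il27ra (0.57 ± 0.07, 22.0 h) and Cry2 (0.53 ± 0.07, 3.6 h) have such an overlap, so that their NTS reads may belong to that gene's TS. In liver Slc13a1, a sulfate transporter, had the widest NTS rhythm of the named genes (2.04 ± 0.17, 12.9 h), followed by Hectd2 (1.78 ± 0.11, 22.7 h, overlapped on the opposite strand) and Ren2 (1.59 ± 0.11, 8.7 h), a renin paralogue whose reads are uncertain. Rhbdd2 (0.98 ± 0.08, 10.0 h) and Tmem263 (0.78 ± 0.07, 19.2 h) were also named there. Over all genes 401 of 18932 were called in kidney, 341 of them with a peak between 16 and 24 h, and 675 of 18061 in liver, with 301 between 16 and 24 h and 287 between 4 and 12 h. Without genes that overlap the opposite strand 445 were called in liver.

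Of the clock lists, 1 of 7 activators and 5 of 14 repressors were called on the kidney NTS (3 and 10 adjusted over the list alone), and 5 of 7 and 7 of 14 on the liver NTS (6 and 10 over the list alone). With the replicate number as a block 1473 genes were called in kidney, 3 of the activators and 8 of the repressors among them. The kidney count was 1065 without ZT0 replicate 2, 614 without ZT12 replicate 1, 160 and 229 without ZT16 replicates 1 and 2, 120 and 231 without ZT20 replicates 1 and 2, 762 and 233 without ZT4 replicates 1 and 2, and 131 and 87 without ZT8 replicates 1 and 2. The liver count was 1025 without ZT0 replicate 1 and 385 without ZT8 replicate 2.

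The rhythm of the TS/NTS ratio asks whether the strands followed the day differently. In kidney the ratio of Npas2 had an amplitude of log2 1.56 (peak 22.2 h, adjusted p = 1.43e-08, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), Arntl 1.26 (21.9 h), Ciart 1.22 (10.7 h), Per2 0.99 (16.0 h), Nr1d1 0.88 (7.5 h) and Mfrp 0.72 (9.6 h). In liver it was 2.42 for Npas2 (23.0 h), 1.63 for Hectd2 (11.4 h), 1.30 for Ciart (11.2 h), 1.25 for Loxl4 (22.5 h), 1.25 for the thyroid hormone receptor gene Thra (20.5 h) and 1.07 for the junction gene Tjp3 (21.4 h). Ciart, Nr1d1, Hectd2, Thra and Tjp3 overlap an opposite-strand gene. Nr1d1 and Thra peaked on their NTS far from their TS, in liver at 22.4 h against 7.2 h and at 7.6 h against 22.8 h. The NTS peak of each thus lay near the TS peak of the other, and their NTS reads may belong to the TS of an overlapping gene. The test called 294 of 19756 genes in kidney (3548 with the replicate number as a block) and 1175 of 19256 in liver. With the times exchanged within a replicate number, 2 of 40 regroupings, the real one included, gave as many kidney genes (highest of the others 386), so chance was not excluded for the kidney count. The kidney count was 150 and 2792 without ZT0 replicates 1 and 2, 116 without ZT12 replicate 2, 66 and 89 without ZT16 replicates 1 and 2, 45 and 82 without ZT20 replicates 1 and 2, 1130 and 90 without ZT4 replicates 1 and 2, and 66 and 44 without ZT8 replicates 1 and 2. The liver count was 730 without ZT20 replicate 1 and 542 without ZT8 replicate 2.

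Between the tissues, the widest differences in TS reads included genes known as renal or hepatic. Miox, a renal inositol oxygenase, had 81.7-fold more TS reads in kidney (log2 6.35 ± 0.14 SE, 12 libraries each, adjusted p = 1.43e-17, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), on 46 liver reads in all. The brush border gene Ush1c (6.42 ± 0.16), the transcription factor gene Tfap2b (6.21 ± 0.14), Guca2b (6.14 ± 0.27), Tmem174 (6.32 ± 0.21), Pantr2 (6.26 ± 0.13) and Tmem252 (6.53 ± 0.22) were also far higher in kidney. In liver Mat1a, the hepatic methionine adenosyltransferase, was 76.4-fold higher (log2 -6.26 ± 0.16), with Sftpa1 (-6.58 ± 0.19) and Wfdc21 (-6.15 ± 0.19). Serpina3k (-6.35 ± 0.21), Mup3 (-6.64 ± 0.31), Cyp2a22 (-6.39 ± 0.25), Cyp2a12 (-6.32 ± 0.18) and Cyp2b9 (-6.03 ± 0.18) were as high in liver but have close paralogues, so their reads are uncertain. Over all genes 8310 were higher in kidney and 6243 in liver, out of 19702, and all 91 named genes kept their call without any single library, 88 of them also under every other setting at the threshold of 0.05.

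By list, 28 of 30 kidney tubule transport genes were higher in kidney and 1 lower (the same adjusted over the list alone), with Cdh16 at log2 5.54 ± 0.11 and the salt transporter Slc12a1 at 4.30 ± 0.08. All 30 hepatocyte genes were higher in liver (median log2 -3.34), as were 18 of 21 xenobiotic genes, 16 of 22 cholesterol genes, 16 of 17 fatty acid synthesis genes and 12 of 18 fasting genes, each the same over the list alone. Examples were Aox1 (-3.90 ± 0.06), the bile salt pump Abcb11 (-5.08 ± 0.14) and Tat (-5.97 ± 0.17). Genes that move or bind platinum split: the cation transporter Slc22a2 (4.70 ± 0.14) and Ggt1 (5.70 ± 0.12), which cleaves glutathione, were higher in kidney, and Atp7b (-2.67 ± 0.08) and Abcc3 (-2.59 ± 0.07) in liver (9 and 8 of 21). Immediate early genes were higher in kidney in 8 of 15 cases (1 lower), such as Fosb (2.88 ± 0.11), and heat shock genes in 12 of 15, such as Serpinh1 (2.58 ± 0.11). Of the p53 targets 10 were higher in kidney, led by Pmaip1 (3.17 ± 0.11), and 8 in liver, led by Fas (-1.53 ± 0.07). Of 29 repair genes 7 were higher in kidney and 14 in liver (median -0.03), with Ercc1 at 0.60 ± 0.04 and Ddb2 at -0.64 ± 0.08.

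Markers of other cell types also differed by tissue. Cholangiocyte markers were higher in kidney in 6 of 7 cases (median log2 3.75), with Krt7 at 4.69 ± 0.11 and Epcam at 4.56 ± 0.11, both also expressed by kidney epithelium. Podocyte markers gave 4 higher and 2 lower of 7, acinar markers 3 higher of 3, immune markers 3 higher and 9 lower of 15, and the clock activator list 1 higher and 5 lower of 7, the same adjusted over the list alone. Clock repressors gave 7 higher and 1 lower of 14. Endothelial markers gave 3 higher and 2 lower of 14 (2 and 2 over the list alone), with the sinusoidal markers Stab2 (-1.56 ± 0.11) and Lyve1 (-2.10 ± 0.19) higher in liver, and mesenchymal markers 3 and 6 of 12 (4 and 6 over the list alone). On the NTS 6489 genes were higher in kidney and 6154 in liver, out of 19124. Among them were Tmem174 (5.81 ± 0.34), Pantr2 (5.34 ± 0.17) and B3gat1 (5.32 ± 0.24) in kidney and Mup21 (-6.69 ± 0.35, uncertain because of its paralogues), Dnase2b (-6.03 ± 0.15), Gpx5 (-5.89 ± 0.15) and Rgr (-5.50 ± 0.14) in liver. With library sizes from TS plus NTS reads the NTS split was 10392 higher and 3203 lower, as the median of all genes moved from log2 0.02 to 0.33.

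A TS rhythm that differed between kidney and liver by the test of the difference itself was called for 185 of 19702 genes, against 670 with DESeq2 and 283 with a mean of at least 50 reads. Gfod1 had an amplitude of log2 0.22 in kidney and 0.78 in liver (adjusted p of the difference 2.40e-06, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Ndrg1, a stress-responsive gene, had 0.02 in kidney and 0.69 in liver, Arhgap24 0.10 and 0.79, and Gas7 0.09 and 1.01. Loxl4 had 0.36 in kidney and 1.31 in liver. Col18a1, which encodes a basement membrane collagen, had 0.37 in kidney and 0.10 in liver. Of the clock activator list 2 of 7 differed (3 adjusted over the list alone), of the clock repressor list 1 of 14 (5 over the list alone) and of the cholesterol genes 3 of 22 (7 over the list alone). The count was 122 and 112 without kidney ZT8 replicates 1 and 2, and 400 and 356 without liver ZT0 replicates 1 and 2.

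For kidney, tables drawn down by the authors to 1 depth per replicate also counted intergenic reads and reads of overlapping genes. Read density in RPKM was 0.747 ± 0.0166 (SD, n = 12) on the TS, 0.101 ± 0.0101 on the NTS and 0.0502 ± 0.00232 per strand between genes. The intergenic share of these reads was 15.8% ± 0.732, with an amplitude of 0.748 ± 0.217 points and a peak at 8.2 h (permutation p = 0.026, adjusted over the 4 classes 0.064). The TS share was 60.5% ± 1.34 (amplitude 1.27 points, peak 20.1 h, permutation p = 0.051, adjusted 0.068), the NTS share 8.20% ± 0.821 (0.740 points, 8.0 h, permutation p = 0.075, adjusted 0.075) and that of overlapping genes 15.5% ± 0.216 (0.218 points, 20.2 h, permutation p = 0.032, adjusted 0.064). None of the 4 classes passed after adjustment. With the replicate number as a block all 4 passed, with an adjusted permutation p of 0.013 for the intergenic, TS and NTS classes and 0.016 for the overlapping class. Without kidney ZT20 replicate 1 the intergenic amplitude was 0.669 (permutation p = 0.076) and without ZT8 replicate 2 it was 0.600 (permutation p = 0.081).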

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

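The regrouping of the tissues was chosen only after the results it bears on were seen.

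In 185 genes the TS rhythm differed between kidney and liver by the test of the difference itself, which is what singled them out (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). DESeq2 called 670, and a filter at a mean of 50 reads gave 283. Of the 185, 98 were called rhythmic in liver alone, 41 in kidney alone, 43 in both and 3 in neither, and 135 had the larger amplitude in liver. Peaks lay over 6 h apart in 24 of the 43. The log2 amplitude of the difference was 0.58 for Gfod1, 0.69 for Ndrg1, 0.76 for Arhgap24, 0.93 for Gas7, 0.46 for Col18a1 and 1.03 for the matrix gene Loxl4.

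A mean under 20 TS reads per library in a tissue was found for 1.08% of the 185 genes, which argues against low counts as their source. The liver library ZT0 replicate 1 lay apart on the first principal component, but 100% of the genes were still called without it, among 400 in all, which argues against that library. Of 100 regroupings of the tissues within each time, fitted with each gene's tissue difference held in the offsets, 1 gave as many genes, the real one with 185, and the highest of the others called 80. The real grouping thus called more genes than any random one, but this cannot exclude chance between mice. Regroupings split up the 2 libraries of a tissue and time, and the labels do not say whether these came from separate mice. The other regroupings still called a median of 5571 genes with a rhythm common to both groups. The number was 122 and 112 without kidney ZT8 replicates 1 and 2, and 356 without liver ZT0 replicate 2. A difference in biology between the tissues, which may act through their own transcription, stays open and was not tested.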

How the results depend on the processing

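The NTS share covariate, the removal of genes overlapping the opposite strand, that of the length trend and the block for shares of reads were chosen only after the results were seen. No named gene reversed. The majority of calls turned from lower to higher for liver dusk against dawn with library sizes from TS plus NTS reads (1420 higher, 1315 lower), and from higher to lower for the NTS between tissues with DESeq2 (5649 and 5725), a mean of at least 50 reads (3816 and 3901) and the replicate block (4998 and 5009). Of 5952 values of named genes with 1 library left out, 5411 kept their call and 541 lost it. Of 3198 values under other settings, 2843 kept it, 346 lost it and 9 had no adjusted p from DESeq2.

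A stricter threshold of 0.01 by construction left fewer calls: 968 kidney TS, 84 kidney NTS, 1150 liver TS and 341 liver NTS rhythms. A test for any difference among the 6 times gave 196, 17, 549 and 271. DESeq2 called 635 kidney NTS rhythms, 497 kidney TS/NTS ratio rhythms and 670 differences of rhythm between tissues. The downsampled kidney tables, with fewer reads and genes, gave 228 NTS and 147 ratio rhythms. Library sizes from TS plus NTS reads gave 237 kidney NTS rhythms. Without a filter on low counts there were 1171 kidney NTS, 1156 liver NTS and 502 kidney ratio rhythms. With a mean of at least 50 reads, NTS differences between tissues numbered 7717 of 10355 genes tested, and differences of rhythm 283. TMM over the strand columns gave 670 kidney ratio rhythms. Without genes overlapping the opposite strand there were 195 kidney ratio and 445 liver NTS rhythms, from fewer genes tested. With the NTS share as a covariate 724 kidney and 649 liver TS rhythms were called, and 515 and 378 genes between dusk and dawn. The liver TS share, taken as the median log2 TS/NTS, had an amplitude of 0.0951 and did not pass (permutation p = 0.068). Of the 8 kidney gene lists 1 passed with an estimated correlation and 2 with fry, which called 3 in all, the third being the cholesterol list (adjusted p = 0.0418). Of the 6 liver lists 1 passed with an estimated correlation and 4 with fry, which called 6 in all, with clock activators and acinar markers besides. Apart from the changes shown by construction, the cause was not tested.

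With the replicate number as a block, calls rose to 4900 kidney TS, 1473 kidney NTS and 3548 kidney ratio rhythms and 4157 kidney genes between dusk and dawn, and the kidney TS share passed at an unmoved amplitude of 1.13 points, as did the 4 kidney read classes. Rora passed in kidney, and the kidney list counts printed for rhythms and for dusk against dawn rose, those that moved by over 1.5 times as given beside them. In liver, where the numbers were not taken to pair samples, the block gave 1939 ratio rhythms and a permutation p of 8e-05 for the TS share. For the difference of rhythms between the tissues it called 447 genes. Between the tissues the block also ended the calls of Clock and Ptprb on the TS. It ended no other call of a gene reported here, changed the call of no gene list between dusk and dawn and moved no other count over all genes by over 1.5 times.

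Leaving out 1 library at a time gave these lowest and highest values. Kidney rhythms numbered 908 to 3938 on the TS, 87 to 1065 on the NTS and 44 to 2792 for the ratio, and liver rhythms 1639 to 4514, 385 to 1025 and 542 to 1546. Dusk against dawn gave 94 to 4004 genes in kidney and 679 to 5374 in liver. Strand differences ranged from 17704 to 17807 in kidney and from 17237 to 17315 in liver, tissue differences from 14067 to 15032 on the TS and from 11968 to 12912 on the NTS, and differences of rhythm from 112 to 400. Amplitudes of the TS share ranged from 0.872 to 1.36 points in kidney and from 0.574 to 0.911 in liver, and that of the intergenic share from 0.600 to 0.885. A time left with 1 library was assumed to vary like the others. Depth was lower on the NTS, with 975978 to 3948748 reads in kidney against 6334958 to 24236776 on the TS. Rhythms of log2 0.5 were simulated in genes with a mean of at least 20 reads of the strand. In kidney 83% were recovered on the NTS and 93% on the TS, but in liver 79% and 72%. The median error of their peaks was 0.467 h and 0.303 h in kidney and 0.513 h and 0.377 h in liver.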

Other observations

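The gene length tests, the NTS share covariate and the comparison of the strands in clock genes were chosen only after the results they bear on were seen.

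Clock genes differed in the phase of their NTS reads. Of the 21 members of the fixed clock lists, 11 were called on both strands in liver, with peaks within 3 h of each other in 8 and over 6 h apart in 3, and 6 in kidney, with 3 and 3. The peaks lay close in liver Npas2 (amplitude log2 0.59, peak 23.5 h against 23.2 h on the TS, adjusted p = 2.28e-05 by edgeR's quasi-likelihood test), Nfil3 (0.56, 8.4 h against 9.2 h, adjusted p = 0.000481), Per3 (0.58, 11.4 h against 12.4 h, adjusted p = 0.00729) and Clock (0.25, 20.8 h against 21.1 h, adjusted p = 0.0482), named here after their values were seen. They lay over 6 h apart in Per2 in both tissues (NTS 4.7 h in kidney and 6.2 h in liver, adjusted p = 2.71e-06 and 0.000718, against 13.6 h and 13.5 h on the TS) and in liver Arntl (13.2 h, adjusted p = 0.0167, against 21.9 h), which no annotated gene overlaps on the opposite strand. The others were Nr1d1 in both tissues (21.5 h and 22.4 h, adjusted p = 0.0374 and 0.000373, against 6.7 h and 7.2 h) and kidney Cry2 (3.6 h, adjusted p = 0.000558, against 12.8 h), which such a gene overlaps. Leaving out single libraries was run for kidney Per2 and Cry2 alone among these NTS values, and both kept their calls.

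TS rhythms gathered in 2 phase groups that differed in gene length, and once each library's trend over gene length was removed, both groups were still there, with 573 and 1338 kidney genes of a median 33.6 and 42.4 kb (13.1 and 77.0 kb before) and 837 and 1338 liver genes of 23.3 and 24.8 kb (16.9 and 46.8 kb before). Tables drawn down to 1 depth per replicate number still called 86.1% of the kidney genes present in both with a peak within 3 h. This argues against depth differences among libraries of 1 number, while depth still differed between the numbers. In liver 68.3% of called genes had an amplitude more than 2 standard errors above that of the library's NTS to TS ratio (log2 0.099). The share was 51.3% for peaks between 4 and 12 h and 77.6% between 16 and 24 h, against 15% of all genes tested. Called genes were chosen by a test of the same amplitude, which raises these shares. The values argue against a varying share of NTS-like reads as the whole source for the liver genes above that amplitude, and leave it open for the others. In kidney 40% of genes exceeded that amplitude (0.135), which leaves this source open for the others, and with the NTS share as a covariate, which itself has this 24 h component, 724 kidney and 649 liver genes were called. After removal of the length trend 57.1% of kidney genes (68.1% with the replicate number as a block in both fits) and 69.1% of liver genes were still called with a peak within 3 h, as the median amplitude of the genes went from log2 0.21 to 0.16 and from 0.22 to 0.19, so a length bias may account for part of the calls and cannot be told apart from a rhythm of long genes. A biological difference between times, such as transcription that changes over the day, stays open and was not tested.

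NTS rhythms were weighed against reads that belong elsewhere. Of called genes 40.4% in kidney and 27.0% in liver overlap a gene of the opposite strand, against 17.2% and 17.5% of genes tested (Fisher's exact test across genes, which are not independent, p = 1.93e-28 and 4.73e-10), so the TS of that gene may be the source for part of the calls. The NTS peak lay within 3 h of the gene's own TS peak in 37.1% of kidney genes, and 66 of the 385 with a TS fit were called on the TS. These values argue against TS reads counted on the wrong strand as the source of most kidney calls. In liver the peaks lay that close in 46.1%, with 184 of 655 called on the TS, which leaves this source open. Repair of unannotated antisense transcription is a hypothesis that was not tested.

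Other assignments of the times to the libraries were fitted, and each number of such regroupings includes the real one. In liver 1 of 100 gave as many TS rhythms (3098, highest of the others 438), NTS rhythms (675, 104) and genes between dusk and dawn (2294, 884), and 1 of 40 as many ratio rhythms (1175, 316). This argues against a random assignment of times to these libraries. It cannot exclude chance between mice, because the labels do not say whether the 2 libraries of a time came from separate mice. In kidney 1 of 100 gave as many TS rhythms (2885, highest of the others 2669), 2 gave as many NTS rhythms (401, 1293) and 3 as many genes between dusk and dawn (1133, 2812). These shares do not exclude chance, because a free exchange of times ignores that kidney libraries of the same replicate number deviated together. Regroupings with over 2 times the real NTS and dusk and dawn counts point to that structure. With times exchanged only within a replicate number, 1 of 100 gave as many in each case, and the highest of the others were 2086, 4 and 24. Of 40 regroupings 1 gave as many kidney ratio rhythms (294, highest of the others 3), but within replicate numbers 2 did (386), so chance was not excluded for that count. The strand labels exchanged within libraries gave as many calls in 1 of 40 regroupings in kidney (17715, highest of the others 15086) and in liver (17174, 14933), and the tissue labels exchanged within times in 1 of 40 for TS (14553) and NTS (12643), where the others called no gene.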
